A study of Homo sapiens with 4 samples.

How the data were processed

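Reads were counted per mature miRNA in 4 small-RNA libraries of K562 cells with inducible CRISPR interference against ERH. RNA was extracted with TRIzol and gel-purified small RNA was sequenced, per the labels. The deposited values are raw read counts, one whole number per miRNA and library, with no header. The adapter trimming, aligner, miRNA annotation release and genome build behind these counts are not given in the sources used here, nor is how reads that match several near-identical miRNAs were assigned. Each table has 2368 rows, of which 2366 are human miRNAs and 2 are spike-in RNAs by their names (frog miR-427 and fly miR-14). Of 267 miRNA names in the fixed lists, 43 have no row under that spelling, some being alternative spellings, and they were not analysed here. Totals are therefore sums of the rows used and not the full depth of the libraries.

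Groups came from the labels, with 2 ERH knockdown and 2 control libraries, 1 per guide RNA in each group. A replicate number is a guide RNA and thus its own polyclonal line, so the numbers pair the samples by design. Same-numbered libraries did not deviate together (correlation of their deviations across miRNAs -0.11). Only 1 culture per guide RNA and condition was sequenced, so p-values measure the spread between these libraries. Libraries of 1 group differed by more than sampling noise (chi-square per degree of freedom 3.93 for knockdown and 10.1 for control), so none was counted as a duplicate. The 5 most abundant miRNAs took 53.5% to 59.5% of the reads. A count of 0 allows up to 3 reads, or 1.21 to 2.10 CPM (reads scaled to a common library total). Reads carry no molecular identifiers as far as the labels say, so such limits cover counting error only.

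The following was fixed before the data were examined. Counts without the spike-ins were filtered with filterByExpr of edgeR 4.0.16 in R 4.3.3 (minimum count 10, minimum total 15), which kept 464 miRNAs with 99.9% of the counts, scaled with TMM and fitted with the quasi-likelihood test of knockdown against control, without a block. miRNAs at a Benjamini-Hochberg adjusted p under 0.05 were called. The biological coefficient of variation was 5.08%. Log2 fold changes are knockdown over control with the SE of the fit, and log2 CPM used a prior count of 2. Lists of clusters, families and lineage-enriched miRNAs, 22 in all, were tested with camera (limma 3.58.1, preset correlation 0.01, adjusted over the 22 lists), which asks whether a list moves relative to the other tested miRNAs. With an estimated correlation, camera called 0 lists, and 0 had an unadjusted p under 0.05. Named miRNAs, 85 in all, follow a rule: the members of the first 4 clusters, the 10 largest rises and 10 largest falls that passed and moved the same way within both guide RNAs, the 5 most abundant in controls, and the most abundant members of each other list.

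miRNA names were matched to hairpin genes of GENCODE 29 (GRCh38). Of 2366 names, 2363 matched at least 1 of 1777 hairpin genes. Hairpins within 10 kb on 1 strand were called clustered, and 6 tested miRNAs made from both kinds of locus, or from none, were left out. Fold energies of annotated hairpins came from RNAfold 2.7.2, and plots were drawn with matplotlib 3.10.9.

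The tests were checked on simulated counts for these 464 miRNAs with 200 changed in each of 10 simulations. The main test recovered 87.15% of changes of 1 and 61.46% of changes of 0.5 on the log2 scale, and 2.87% of its calls were false. As many simulated changes went up as down, so these rates do not cover an error of scaling between libraries. camera called all shifted lists of 10 miRNAs and 4% of unshifted ones at an unadjusted p under 0.05. The simulated miRNAs varied independently, so that 4% does not cover lists whose members vary together. In the real lists the estimated correlation ran from -0.33 (miR-144~451a) to 0.97 (miR-221~222). A test of count ratios of 2 miRNAs (limma on log2 ratios) called 59.8% of simulated pairs that parted by 1 and 2.6% of pairs that did not.

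Alternatives fixed beforehand were a replicate block, DESeq2 1.42.0, size factors (RLE), library size alone, spike-in scaling, no filter, a mean of at least 10 CPM, leaving out the most abundant miRNA, leaving out each library in turn, an estimated correlation, and cluster distances of 3 and 50 kb. Chosen after seeing the data were the count ratios of cluster neighbours, the pair tests on hairpins and arms, the other splits of the libraries, the crossed pairing and fry, which tests a list on its own and called 17. The pair test was first run with 1 prior variance for all pairs and called 0 of 336 hairpin pairs and 0 of 109 arm pairs. A depth-dependent prior variance was then tried because of that result. It called 46 and 13, and on simulated pairs it called 68.8% of those that parted and 1.5% of those that did not. The first version is the reported result, and both are given wherever either is used.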

Results

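Small RNAs were sequenced from K562 cells, an established human chronic myeloid leukaemia line with erythroid and megakaryocytic features. The cells carried dCas9-KRAB, a catalytically inactive Cas9 fused to a transcriptional repressor that silences the gene its guide RNA targets (CRISPR interference). Each of 2 guide RNAs against ERH, a small conserved protein that binds the Microprocessor complex (the nuclease that cuts miRNA hairpins out of primary transcripts), had its own polyclonal line. Each line was sampled on day 5 with 0.05 µg/ml doxycycline (ERH knockdown) and without doxycycline (control), which gave 2 libraries per group. The knockdown libraries held 2227374 miRNA reads with guide RNA 1 and 2393565 with guide RNA 2, and the control libraries held 1430434 and 2476700. ERH mRNA was not measured in these libraries, so the extent of knockdown was not checked, and doxycycline without an ERH guide RNA was not analysed here. The comparison asks which miRNAs depend on ERH, and whether a hairpin that lies beside another in the genome depends on it more.

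After ERH knockdown, miRNAs of the miR-17~92a-1, miR-15a~16-1, miR-15b~16-2 and miR-191/miR-425 clusters and the myeloid miRNAs miR-223 and miR-142 fell relative to the bulk of miRNAs, and both arms of miR-144 rose while its neighbour miR-451a fell. With spike-in scaling, most of these falls end or turn positive, as given below. In all, knockdown changed 236 of 464 tested miRNAs at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Of these, 119 rose and 117 fell, and all 236 moved the same way within both guide RNAs. The calls came from these same 4 libraries, so that agreement was likely from the selection alone. A change of at least 1 on the log2 scale was seen for 44 that rose and 19 that fell. Across the tested miRNAs, the log2 ratios of knockdown to control from the 2 guide RNAs had a Pearson correlation of 0.73 and a Spearman correlation of 0.74, and 82.1% had the same sign. These correlations are across miRNAs, which are not independent replicates. The count of calls was 117 without knockdown replicate 1 (49 up, 68 down), 140 without control replicate 2 (48 up) and 146 with DESeq2 (47 up, 99 down), and 70 rose without knockdown replicate 2. The direction of a single miRNA depends on the scaling between libraries. The median log2 fold change of all tested miRNAs was 0.06 with the TMM factors used here, and it lay 0.44 higher with library size alone and 0.68 higher with the added spike-in RNAs. The split of calls was then 273 up and 41 down with library size, and 186 up and 8 down with the spike-ins. Those 8 were miR-1260b, miR-1260a, miR-4443, miR-212-3p, miR-212-5p, miR-34a-5p, miR-21-3p and miR-223-5p, so each other fall named below lost its call with spike-ins. Library size ended the calls of miR-451a, miR-20a-5p, miR-17-5p, miR-17-3p, miR-15b-3p, miR-16-1-3p, miR-16-2-3p, miR-29c-3p and miR-223-3p without turning them positive. Below, "rose" and "fell" are therefore relative to the bulk of tested miRNAs, and ratios of counts within a library need no scaling.

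**Figure D1:**
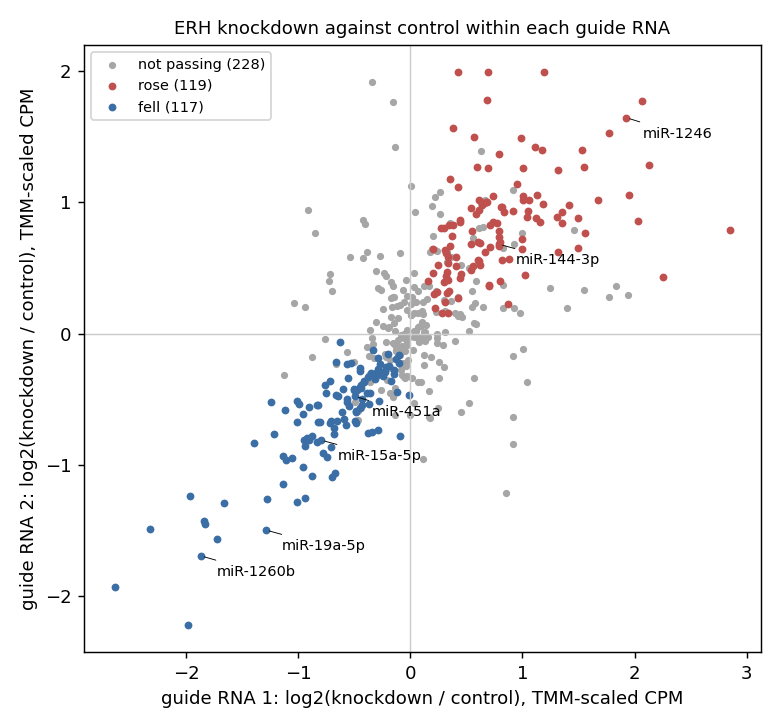
Log2 ratio of ERH knockdown to control for each of 464 miRNAs (points), with guide RNA 1 on the x axis and guide RNA 2 on the y axis, both from TMM-scaled CPM. The 119 miRNAs that rose (red) and the 117 that fell (blue) lie in the upper right and lower left, a split that becomes 273 and 41 with library size alone and 186 and 8 with spike-in scaling.

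The ratio of miR-451a to its neighbour miR-144 was lower after knockdown with both guide RNAs. The miR-144 and miR-451a hairpins lie on the minus strand of chromosome 17 at 28861533-28861618 and 28861369-28861440 (GRCh38, within an exon of the long noncoding RNA AC024267.1). Both are abundant in erythroid cells, and miR-451a is matured by Argonaute 2 instead of Dicer. miR-451a fell by 0.48 ± 0.05 on the log2 scale (SE, 2 libraries per group), with 53617 and 57755 reads after knockdown and 36108 and 60800 in controls; with spike-in scaling its value was 0.21, with library size it was -0.05, and neither was called. miR-144-3p rose by 0.74 ± 0.05 and miR-144-5p by 0.88 ± 0.06, and miR-144-3p stayed up under each scaling. There were 41660 and 40602 reads of miR-144-3p after knockdown against 11527 and 19156 in controls. Within a library, the count of miR-451a per count of miR-144-3p was 1.35 ± 0.10 after knockdown and 3.15 ± 0.03 in controls (SD, n = 2), 2.33-fold lower and far outside the spread between libraries. An exact permutation test of 2 libraries against 2 cannot give a two-sided p under 0.333. All 3 tested members of this list passed, with 2 up and 1 down, and the list as a whole was not called (camera, adjusted p = 0.46). The list was chosen with miR-451a in mind, from what is remembered of the study, so it is not independent evidence of its direction.

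**Figure D2:**
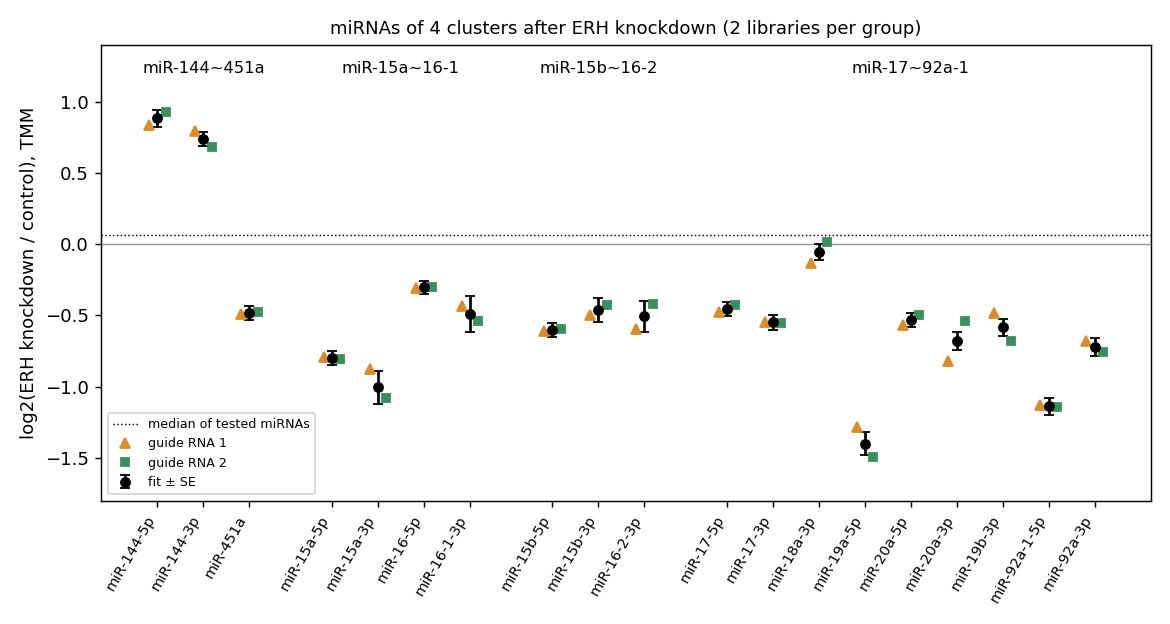
Log2 fold change of ERH knockdown over control (y axis, TMM scaling) for the tested miRNAs of 4 clusters (x axis), as the fitted value with its SE (black) and the ratio within each guide RNA (triangles and squares). miR-144-5p and miR-144-3p lie at 0.88 and 0.74 and miR-451a at -0.48, a value that turns to 0.21 with spike-in scaling.

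The hairpin pairs miR-15a~16-1 and miR-15b~16-2 fell together relative to the bulk of miRNAs. miR-15a-5p and miR-16-5p target cell cycle and survival genes and come from the DLEU2 transcript, with MIR15A at chromosome 13, 50049119-50049201 (exon) and MIR16-1 at 50048973-50049061 (intron), on the minus strand. miR-15a-5p fell by 0.80 ± 0.05 and miR-15a-3p changed by -1.005 ± 0.12, while miR-16-1-3p fell by 0.49 ± 0.13 (0.19, not called, with spike-ins). miR-16-5p, which is made from 2 loci and whose reads cannot be split between them, fell by 0.30 ± 0.05, a value that turns to 0.13, and is called, with library size and to 0.39, not called, with spike-ins. The count of miR-15a-5p per miR-16-5p was 0.206 ± 0.002 after knockdown and 0.291 ± 0.001 in controls (SD, n = 2). All 4 members of the miR-15a~16-1 list fell (camera, adjusted p = 0.026; adjusted p = 0.53 with an estimated correlation). As with miR-451a, miR-15a was remembered from the study, so this list is not independent evidence either. The miR-15b~16-2 pair lies within an intron of SMC4 at chromosome 3, 160404588-160404825. There, miR-15b-5p fell by 0.60 ± 0.05, miR-15b-3p by 0.46 ± 0.09 and miR-16-2-3p by 0.51 ± 0.11, each of which was positive and not called with spike-in scaling. All 4 list members fell (camera, adjusted p = 0.026; adjusted p = 0.53 with an estimated correlation), and the list lost its call with library size.

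**Figure D3:**
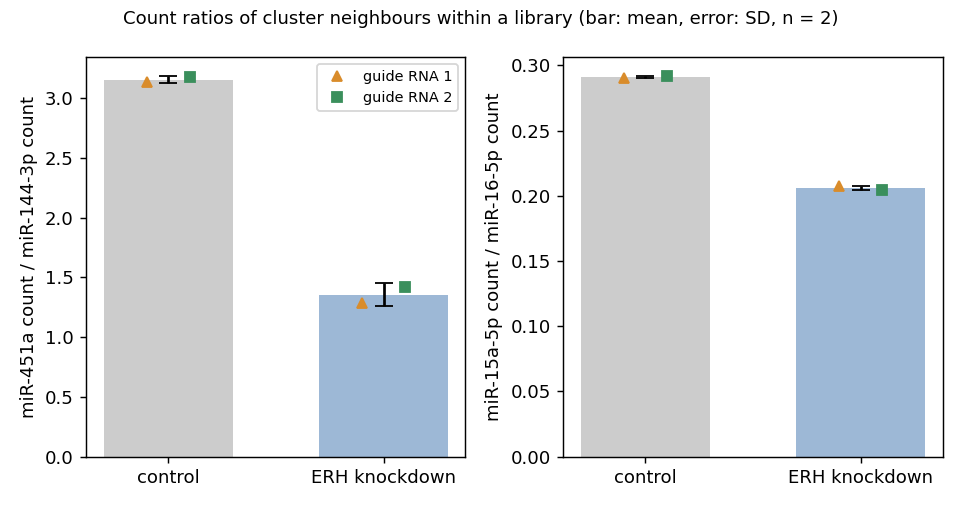
Count of miR-451a per count of miR-144-3p (left) and of miR-15a-5p per count of miR-16-5p (right) in control and ERH knockdown libraries, as the mean (bar), the SD (n = 2) and the value for each guide RNA (symbols). Both ratios were lower after knockdown, at 1.35 against 3.15 and at 0.206 against 0.291, and neither depends on scaling between libraries.

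All pairs of hairpins of 1 cluster, where neighbours in the chain lie within 10 kb, were then compared by the change in their count ratio, a test added after the data were seen. Of these pairs, 253 came from the large chromosome 19 miRNA cluster, whose members are low in count and can lie farther apart, so that cluster weighs heavily on the adjustment. Each hairpin stood for its most abundant tested miRNA. Some hairpins had only 1 tested arm, so their ratios can reflect arms as well as hairpins. Among these, miR-19a, miR-23a, miR-27a, miR-27b and miR-132 stood by the 5p arm, and miR-18a, miR-424, miR-30b and let-7d by the 3p arm. With limma on log2 ratios and 1 prior variance for all pairs, 0 of 336 pairs in 38 clusters passed, while 69 had an unadjusted p under 0.05. The ratio of miR-144-3p to miR-451a differed by 1.22 ± 0.16 (log2, SE) and ranked 3rd by p, at an adjusted p of 0.126. A second version, in which the prior variance follows read depth, was run only after the first had called none. It called 46 pairs in 20 clusters and ranked this pair 1st (SE 0.07, adjusted p = 1.49e-10), so whether single pairs pass depends on that choice. Other neighbours, picked after their values were seen, parted as far. The log2 ratio of miR-132-5p to miR-212-3p changed by 1.56 ± 0.18 and that of miR-18a-3p to miR-19a-5p by 1.34 ± 0.18 (SE). That of miR-192-5p to miR-194-5p, which has 2 loci, changed by -1.21 ± 0.17. These 2 miRNAs stood at -0.70 and 0.52, both called. In the first limma version each pair had an adjusted p of 0.126. In the second it was 5.1e-04, 1.2e-09 and 4.9e-09.

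The miR-17~92a-1 cluster, an oncogenic polycistron of 6 hairpins in an exon of MIR17HG (chromosome 13, 91350605-91351391), fell. Of 9 tested members 8 fell and 0 rose (camera, adjusted p = 0.0011; adjusted p = 0.53 with an estimated correlation). The largest falls were in the less abundant arms miR-19a-5p (-1.40 ± 0.08) and miR-92a-1-5p (-1.14 ± 0.06). Among the most abundant miRNAs of the cells, miR-92a-3p fell by 0.72 ± 0.06, miR-19b-3p by 0.58 ± 0.06, miR-20a-5p by 0.53 ± 0.05 and miR-17-5p by 0.45 ± 0.05. miR-20a-3p stood at -0.68 ± 0.07 and miR-17-3p at -0.55 ± 0.05. miR-18a-3p was the exception, at -0.06 ± 0.06 (adjusted p = 0.41; 0.38 and called with library size). The other arms miR-18a-5p and miR-19a-3p were not tested, so miR-18a and miR-19a are judged by 1 arm each. With spike-in scaling, miR-19b-3p, miR-20a-5p, miR-20a-3p, miR-17-5p and miR-17-3p had positive values that were not called. miR-19b-3p and miR-92a-3p are also made from the miR-106a/miR-363 cluster on chromosome X, and they were the 2 of its 3 tested members that fell (camera, adjusted p = 0.060); miR-106a-5p stood at -0.42 ± 0.32.

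Of the related miR-106b~25 cluster in an intron of MCM7, 5 of 6 members fell (camera, adjusted p = 0.052; 0.048 with guide RNA as a block; adjusted p = 0.53 with an estimated correlation). miR-25-5p fell by 1.47 ± 0.10, against 0.31 ± 0.05 for miR-106b-5p, 0.23 ± 0.06 for miR-25-3p and 0.17 ± 0.05 for miR-93-5p, which turn positive with library size (called) and with spike-ins (not called); miR-93-3p fell by 0.29 ± 0.10. Without knockdown replicate 1 miR-106b-5p (-0.29), miR-25-3p (-0.21) and miR-93-5p (-0.17) were not called; miR-25-3p and miR-93-5p were also lost without knockdown replicate 2 (-0.27 and -0.17) or control replicate 2 (-0.14 and -0.12). In the miR-191/miR-425 cluster all 4 members fell (camera, adjusted p = 0.026; adjusted p = 0.53 with an estimated correlation). miR-425-5p fell by 0.90 ± 0.06 and miR-191-5p by 0.35 ± 0.05, miR-191-3p by 0.88 ± 0.16 and miR-425-3p by 0.41 ± 0.13. miR-191-5p and miR-425-3p turn positive, uncalled, with library size and with spike-ins, and miR-425-3p was not called by DESeq2 or without either knockdown replicate (-0.46 and -0.39) or control replicate 2 (-0.34). The count of miR-425-5p per miR-191-5p was 0.279 ± 0.012 after knockdown and 0.406 ± 0.010 in controls (SD, n = 2).

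In the let-7 family, known for repressing growth genes, 4 of 11 members fell, namely let-7g-5p (-0.43 ± 0.08), let-7e-3p (-0.75 ± 0.20), let-7d-3p (-0.84 ± 0.32) and miR-98-5p (-0.57 ± 0.18), while let-7e-5p was at -0.08 ± 0.06 and let-7f-5p at -0.09 ± 0.06 (camera for the list, adjusted p = 0.033; adjusted p = 0.53 with an estimated correlation). In the miR-30 family 4 of 6 fell, namely miR-30e-5p (-0.42 ± 0.05), miR-30d-5p (-0.31 ± 0.05), miR-30b-3p (-0.86 ± 0.18) and miR-30d-3p (-0.60 ± 0.16) (camera for the list, adjusted p = 0.033; adjusted p = 0.53 with an estimated correlation); miR-30e-3p was at -0.00 ± 0.07. let-7g-5p, miR-30e-5p and miR-30d-5p have positive values, none called, with library size and with spike-ins. let-7e-5p, let-7f-5p and miR-30e-3p are positive with both and called with library size. Both list calls are lost with library size and with the filter of at least 10 CPM, that of let-7 also without knockdown replicate 2 and that of miR-30 without control replicate 2.

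Other clusters were not called as lists by camera. Of the miR-232724 clusters 3 of 5 members fell (camera, adjusted p = 0.059), with miR-23a-5p at -1.05 ± 0.15, miR-27a-5p at -0.98 ± 0.15 and miR-27b-5p at -0.94 ± 0.33, whereas their neighbour miR-24-3p was at -0.11 ± 0.05. Only 7 of the 11 names in this list had rows, and no 3p arm of miR-23 or miR-27 was tested. In controls, miR-23a-5p and miR-27a-5p had means of 81 and 84 CPM, against 5513 for miR-24-3p. The comparison therefore cannot tell a difference between arms from 1 between hairpins. Among the miR-29 clusters 4 of 7 fell (adjusted p = 0.23), with miR-29c-3p at -0.54 ± 0.06, miR-29a-3p at -0.36 ± 0.06, miR-29b-1-5p at -0.73 ± 0.20 and miR-29c-5p at -0.53 ± 0.19, and with miR-29b-3p not called, at 0.04 ± 0.05. miR-221-3p (-0.42 ± 0.06) and miR-222-3p (-0.33 ± 0.06) were the 2 of 3 members of their cluster that fell (adjusted p = 0.12), and miR-221-5p was at -0.35 ± 0.26. In the miR-424~450b cluster 2 of 6 fell (adjusted p = 0.41), namely miR-424-3p (-0.88 ± 0.12) and miR-450a-5p (-0.28 ± 0.09); miR-503-5p was at -0.13 ± 0.09. miR-29a-3p, miR-221-3p, miR-222-3p and miR-450a-5p turn positive, uncalled, with library size and with spike-ins, and miR-29c-3p with spike-ins. miR-24-3p and miR-503-5p are positive and called with library size, as miR-29b-3p is. miR-450a-5p was not called by DESeq2, without a filter or without any 1 library, and miR-222-3p not without knockdown replicate 1 (-0.31).

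The miR-532/miR-502 cluster on chromosome X had 2 up and 2 down of 12 (adjusted p = 0.65; median 0.02, mean -0.06), namely miR-188-5p (0.25 ± 0.08), miR-501-3p (0.28 ± 0.10), miR-532-5p (-0.80 ± 0.10) and miR-532-3p (-0.74 ± 0.08), and miR-660-5p was at 0.03 ± 0.07, miR-362-3p at -0.10 ± 0.07 and miR-362-5p at -0.13 ± 0.07. The miR-181 clusters had 1 up and 1 down of 4 (adjusted p = 0.49); miR-181a-5p rose by 0.38 ± 0.14 and miR-181b-5p fell by 0.87 ± 0.23, while miR-181c-5p was at -0.15 ± 0.15 and miR-181d-5p at -0.23 ± 0.23. In the miR-183/miR-96/miR-182 cluster 0 of 5 members passed in edgeR or in DESeq2, and 0 had an unadjusted p under 0.05 in edgeR (list, adjusted p = 0.61). There, miR-96-5p was at -0.03 ± 0.05, miR-182-5p at 0.07 ± 0.08 and miR-183-5p at 0.08 ± 0.07. miR-96-5p, miR-362-3p and miR-362-5p turn positive, and miR-182-5p, miR-183-5p and miR-660-5p pass, with library size. miR-181a-5p was not called with the block, RLE or DESeq2, or without either knockdown replicate (0.37 and 0.38) or control replicate 2 (0.31).

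Among lineage-enriched lists, all 4 tested myeloid-enriched miRNAs fell (camera, adjusted p = 0.026; adjusted p = 0.53 with an estimated correlation). miR-223-3p, a granulocyte miRNA, fell by 0.54 ± 0.05 and its other arm miR-223-5p by 1.64 ± 0.10, while miR-142-3p fell by 0.54 ± 0.05 and miR-142-5p by 0.56 ± 0.05. With spike-ins, miR-223-3p, miR-142-3p and miR-142-5p were positive and not called, and the list lost its call without knockdown replicate 1. Of the 7 erythroid-enriched miRNAs 2 rose (both miR-144 arms) and 3 fell (adjusted p = 0.78; median -0.05, mean 0.03). Besides miR-451a, miR-486-3p fell by 0.70 ± 0.07 and miR-22-3p by 0.23 ± 0.06, a fall smaller than the shift of 0.44 that library size brings. miR-486-5p was at -0.05 ± 0.06 (0.39 and called with library size) and miR-210-3p at 0.09 ± 0.09. Of 4 megakaryocyte- or endothelium-enriched miRNAs 3 fell (adjusted p = 0.12), namely miR-146b-5p (-0.69 ± 0.06), miR-126-3p (-0.27 ± 0.05) and miR-126-5p (-0.26 ± 0.05), the last 2 positive and called with library size and all 3 positive and uncalled with spike-ins; both miR-126 arms were not called without knockdown replicate 1 (-0.26 and -0.25). Of 4 tested miRNAs of other cell types 2 rose (adjusted p = 0.48), namely miR-145-5p (0.26 ± 0.06) and miR-200c-3p (0.35 ± 0.14), and miR-9-5p was at -0.20 ± 0.09 (0.25 and called with library size). miR-145-5p was not called without either knockdown replicate (0.25 in each) or control replicate 2 (0.19), and miR-200c-3p not with the block, RLE, DESeq2 or no filter, or without any 1 library. miR-486-3p, miR-22-3p and miR-210-3p, and in other lists miR-93-3p, miR-191-3p, miR-27b-5p, miR-181b-5p, let-7e-3p, let-7d-3p, miR-98-5p, miR-29b-1-5p, miR-29c-5p, miR-30b-3p, miR-30d-3p, miR-188-5p, miR-501-3p, both miR-532 arms and miR-877-3p, were added to the named miRNAs after their values were seen, and for those that fell by less than 0.44 the shift with library size exceeds the fall.

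Hairpins that bypass the Microprocessor are a natural contrast to those that need it. Of 6 tested miRNAs from mirtrons (hairpins released by splicing) and capped hairpins, 2 rose and 0 fell in edgeR, and DESeq2 called 0 of the 6 (3 had an unadjusted p under 0.05 in edgeR). Their median log2 fold change was 0.54 (camera, adjusted p = 0.17). miR-877-5p and miR-877-3p, from a mirtron of ABCF1, rose by 0.51 ± 0.15 and 0.82 ± 0.21; miR-877-5p was not called without knockdown replicate 1 (0.46) or control replicate 1 (0.40). The mirtron miR-1226-3p was at 0.21 ± 0.16 (called with library size and spike-ins) and miR-484, from a capped hairpin, at -0.11 ± 0.06 (0.33, and called, with library size). The list of textbook solo hairpins had 23 down and 7 up of 59, with a median of -0.14 (camera, adjusted p = 0.026; adjusted p = 0.53 with an estimated correlation). That call is lost with library size and with the filter of at least 10 CPM. Lists were not matched on abundance in camera, and abundant miRNAs tended to lie lower, so abundance may add to this call. Adjusted over the list alone, the number of calls was that over all tested miRNAs in each of the 22 lists except miR-106b~25 (6 instead of 5), let-7 (3 instead of 4) and solo hairpins (31 instead of 30).

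Among the largest changes were miR-1260b, which fell by 1.78 ± 0.07 from 3081 ± 81 to 899.7 ± 101 CPM (SD, n = 2), and miR-1246, which rose by 1.82 ± 0.14 from 158 ± 16 to 554 ± 132. miR-21-3p, the minor arm of a miRNA high in many tumours, fell by 1.64 ± 0.10, and miR-34a-5p, a p53 target, fell by 1.81 ± 0.34. miR-3187-3p rose by 1.90 ± 0.17 from 22.1 ± 4.3 to 85.2 ± 3.9 CPM. These 5 keep their direction under each scaling. Whether their reads come from hairpins cut by the Microprocessor or from fragments of other RNAs was not tested. The predicted fold was -0.25 kcal/mol per nucleotide for MIR1246 and -0.46 for MIR1260B. Among the rarer miRNAs below, MIR6516 overlaps an exon of SCARNA16, another small-RNA gene. The 10 largest falls also held miR-223-5p, miR-25-5p and miR-19a-5p, given above, and the rarer miR-4443 (-3.12 ± 0.56), miR-1260a (-2.61 ± 0.43), miR-212-5p (-2.44 ± 0.57) and miR-212-3p (-1.65 ± 0.30). Likewise, the other large rises ran from 1.60 to 1.99 and came from miR-3144-3p, miR-520a-3p, miR-149-5p, miR-3944-3p, miR-3609, miR-520d-5p, miR-1914-5p and miR-6516-5p, of which miR-3144-3p had 13 and 20 reads after knockdown and 1 and 4 in controls. At such counts single libraries decide: miR-3144-3p, miR-520a-3p, miR-3609, miR-1914-5p and miR-6516-5p were not called without any 1 of the 4 libraries, and miR-149-5p without 3 of them. Without control replicate 2, the log2 fold change of miR-3944-3p was 1.59 and the log2 fold change of miR-1260a was -2.22, neither called. Without knockdown replicate 1, the log2 fold change of miR-212-3p was -1.73 and the log2 fold change of miR-212-5p was -1.77, neither called, and miR-212-5p was not called without control replicate 1 either (-2.55). DESeq2 did not call miR-3144-3p, miR-520a-3p, miR-3609, miR-1914-5p, miR-6516-5p, miR-149-5p, miR-4443 or miR-212-5p.

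The median of miRNAs from clustered hairpins lay below that from single hairpins. The median log2 fold change was -0.16 for 171 miRNAs whose hairpins have a neighbour within 10 kb on the same strand (33 rose, 68 fell) and 0.17 for 287 single-hairpin miRNAs (86 rose, 49 fell). The difference of the medians, which a change of scaling moves little, was -0.33 (camera, p = 4.62e-05; p = 0.035 with an estimated correlation). Both classes spread widely, with interquartile ranges from -0.53 to 0.33 and from -0.20 to 0.68. Clustered miRNAs were also more abundant, with a median of 6.01 against 4.76 log2 CPM, and abundance itself went with the change. Against single-hairpin miRNAs matched in 6 abundance classes, of which the highest spans 9.88 to 17.41 log2 CPM, the difference was -0.26. The fixed list of textbook solo hairpins, with 59 tested miRNAs, had a median of -0.14, close to that of clustered miRNAs. It was fixed by name and not by the 10 kb rule, and it holds both miR-142 arms, which that rule counts as clustered.

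**Figure D4:**
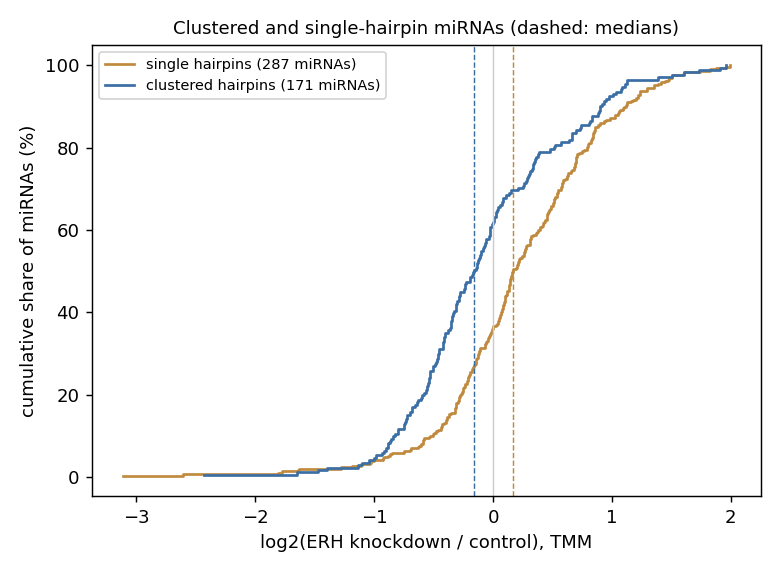
Cumulative share of miRNAs (y axis, %) by log2 fold change of ERH knockdown over control (x axis, TMM scaling) for 171 clustered and 287 single-hairpin miRNAs, with medians dashed. The clustered curve lies to the left, with medians of -0.16 and 0.17, both of which are positive once the shift of 0.44 with library size or 0.68 with spike-ins is added.

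The arms of a hairpin mostly moved together. Both arms were tested for 109 hairpins, and in 88 (80.7%) their log2 fold changes had the same sign. Of 40 hairpins with both arms called, 39 had the same sign, with 12 up and 27 down. The 4 pairs with the smallest p were those of miR-942, miR-3944, miR-25 and miR-223. The change with knockdown in the log2 ratio of their arms (3p to 5p for miR-942, 5p to 3p for the others) was estimated at -1.31 ± 0.16, -1.88 ± 0.26, -1.25 ± 0.19 and -1.09 ± 0.19 (SE). With the depth-dependent prior variance the SEs were 0.30, 0.47, 0.15 and 0.13. The lowest count in any library was 17 for miR-942 and 5 for miR-3944, against 289 for miR-25 and 781 for miR-223. A prior variance shared by all pairs may thus understate the error for miR-942 and miR-3944. With limma and 1 prior variance for all pairs 0 of 109 arm pairs passed (21 had an unadjusted p under 0.05), and with the depth-dependent prior variance, run after that result was seen, 13 passed, these 4 among them.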

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

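For 5 named miRNAs the 2 guide RNAs moved in opposite directions. Each value is the log2 ratio of knockdown to control with guide RNA 2 minus that with guide RNA 1, and each guide RNA has 1 library per condition, so these differences were not tested. The difference was 0.39 for miR-181c-5p (-0.36 with guide RNA 1 and 0.03 with guide RNA 2) and 0.32 for miR-182-5p (-0.10 and 0.22). It was 0.15 for miR-18a-3p (-0.13 and 0.02), -0.14 for miR-30e-3p (0.08 and -0.07) and -0.15 for miR-486-5p (0.02 and -0.12). None of these 5 passed the test of knockdown against control in edgeR with TMM scaling. With 2 libraries per group, no library could be set apart as an outlier.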

How the results depend on the processing

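The crossed pairing and the pair tests were chosen after the data were seen, and the other alternatives before. Among miRNAs called in both, 0 had changed direction under the replicate block, DESeq2, RLE size factors, no filter, the filter of at least 10 CPM, leaving out the most abundant miRNA, spike-in scaling or leaving out any library, against 15 with library size. The replicate block (paired by guide RNA) called 230 miRNAs, 226 of them shared with the unpaired fit in the same direction. It moved no count by over 1.5 times, and among named results it ended the calls of 2 miRNAs and added that of the miR-106b~25 list (adjusted p = 0.048; adjusted p = 0.53 with an estimated correlation). A crossed pairing, added because the deviations of same-numbered libraries had a weak negative correlation (-0.11), called 241. RLE called 236, no filter 237, the filter 213 and leaving out the top miRNA 235. DESeq2 called 146 (47 up), with 54 adjusted p-values not given, and kept 143 of the calls in the same direction; beyond those the cause was not tested.

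Scaling decides directions, since it shifts every miRNA alike. Library size called 314 (273 up, 41 down) and spike-ins 194 (186 up, 8 down). The 2 spike-ins disagree on the shift, with -0.81 and -1.08 for miR-14 against -0.69 and -0.63 for miR-427 within the guide RNAs. Among named miRNAs called with TMM or with the alternative, these log2 fold changes turned positive with library size: miR-16-5p 0.13, miR-18a-3p 0.38, miR-106b-5p 0.12, miR-25-3p 0.21, miR-93-5p 0.27, miR-24-3p 0.33, let-7e-5p 0.36, let-7f-5p 0.35, let-7g-5p 0.012, miR-362-3p 0.34, miR-362-5p 0.31, miR-503-5p 0.31, miR-450a-5p 0.16, miR-221-3p 0.019, miR-222-3p 0.11, miR-96-5p 0.41, miR-191-5p 0.083, miR-425-3p 0.031, miR-29a-3p 0.072, miR-30e-5p 0.013, miR-30d-5p 0.13, miR-30e-3p 0.44, miR-484 0.33, miR-486-5p 0.39, miR-126-5p 0.18, miR-126-3p 0.17, miR-9-5p 0.25. With spike-ins these did, and other named negative values that pass under neither scaling are positive too: miR-15b-5p 0.087, miR-20a-5p 0.16, miR-20a-3p 0.028, miR-17-3p 0.14, miR-451a 0.21, miR-19b-3p 0.093, miR-17-5p 0.24, miR-16-5p 0.39, miR-15b-3p 0.23, miR-16-2-3p 0.19, miR-16-1-3p 0.19, miR-142-3p 0.14, miR-106b-5p 0.38, miR-25-3p 0.45, miR-93-5p 0.52, let-7g-5p 0.26, miR-450a-5p 0.41, miR-221-3p 0.27, miR-222-3p 0.36, miR-191-5p 0.34, miR-425-3p 0.27, miR-29a-3p 0.34, miR-29c-3p 0.15, miR-30e-5p 0.27, miR-30d-5p 0.38, miR-223-3p 0.15, miR-142-5p 0.14, miR-146b-5p 0.019, miR-126-5p 0.43, miR-126-3p 0.42.

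Leaving out 1 library gave 117 to 195 calls, 48 to 84 up and 68 to 111 down, the lowest totals without knockdown replicate 1 (117) and control replicate 2 (140); the lone library is then assumed to vary like the other group. The gap between clustered and single-hairpin miRNAs ran from -0.38 to -0.31 and the list calls from 7 to 10. The gap was -0.30 at 3 kb and -0.34 at 50 kb. camera called 8 lists, 5 with library size, 5 with the stricter filter and 0 with an estimated correlation and the cause was not tested. Agreement between guide RNAs was 0.84 with the stricter filter, which drops low-count miRNAs, and leaving out a library gives it no value.

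The pair test depends on its variance model. limma with 1 prior variance called 0 of 336 hairpin pairs and 0 of 109 arm pairs (69 and 21 at an unadjusted p under 0.05), and the depth-dependent version, tried because of those counts, called 46 and 13. Depth limits the rarest miRNAs, where a few reads set a log2 fold change.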

Other observations

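The chromosome 19 miRNA cluster (C19MC, 35 hairpins at 53666679-53761222, GRCh38), which is active mainly in placenta, rose after ERH knockdown although it is clustered. Of 27 tested members 17 rose and 0 fell, with a median log2 fold change of 0.89 and a lowest value of 0.14. The number that fell was 0 with RLE, library-size and spike-in scaling too. That adds no support, since these scalings shift every miRNA nearly alike, by -0.05, 0.44 and 0.68. Examples are miR-520d-5p (1.73 ± 0.30, SE), miR-498 (1.39 ± 0.27) and miR-515-3p (1.04 ± 0.24). The miR-548 family, scattered over the genome and derived from a transposon, behaved alike, with 12 up and 0 down of 22 and a median of 0.69, led by miR-548l (1.47 ± 0.14). Both sets are low, with medians of 15.2 and 19.8 CPM. Both lists were chosen after their values were seen, and camera gave p = 1.78e-06 and p = 2.73e-04 (p = 0.040 and p = 0.057 with an estimated correlation).

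All tests in this part, camera on these lists included, were chosen after the results were seen, except those on abundance taken from the other control library and on abundance-matched single-hairpin miRNAs, which were set down before their outcomes.

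The rise of C19MC and miR-548 miRNAs could come from a general trend toward higher values among low-count miRNAs. Against 10000 lists matched on abundance, the C19MC median stood at percentile 99.97 and the miR-548 median at 99.71. Both lists were chosen after their values were seen, so a high percentile was likely from the choice alone. It cannot decide whether abundance is the whole cause. Reads moved between near-identical members would leave the family total level, yet the TMM-scaled count summed over all 39 and 48 members, untested ones included, was higher by 0.85 (C19MC) and 0.56 (miR-548) on the log2 scale, and higher within both guide RNAs. Fragments of other repeat-rich transcripts counted as these miRNAs stay open, as does an effect of ERH loss on their transcription, which was not tested.

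The parting of miR-144 and miR-451a was weighed next. An error in 1 arm of miR-144 is argued against by the rise of both arms, which differed by 0.15. A change in the shared primary transcript alone would move both neighbours alike if the mature miRNAs decay at equal rates, which was not measured. The log2 ratio of miR-144-3p to miR-451a was higher by 1.22 ± 0.16 (SE), by 1.28 and 1.16 within the guide RNAs. With spike-in scaling miR-451a stood at 0.21 and miR-144-3p at 1.42, both positive. The ratio thus argues against a change in the transcript alone only if decay is equal. The adjusted p of that pair was 0.126 in the limma test run first and 1.49e-10 in the depth-dependent version chosen after it. A candidate explanation is that cutting of the miR-451a hairpin needs ERH and that more of the transcript is made, but primary transcripts were not measured here, and a difference in the decay of the mature miRNAs stays open.

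Log2 fold change went down with abundance, with medians from 0.50 in the lowest of 6 abundance classes to -0.23 in the highest. Library depth would leave little trend with guide RNA 2, whose libraries held 2393565 and 2476700 reads, but the rank correlation across miRNAs of ratio with abundance was -0.34 there. With abundance from the control of the other guide RNA it was -0.41 or stronger. That cannot rule out counting noise, because a miRNA below the filter cutoff in both controls was kept only if both knockdown libraries reached it. An example is miR-520a-3p, with 15 and 11 reads after knockdown and 0 and 4 in controls. Among names numbered below 1000 the rank correlation of log2 fold change with abundance was -0.31, against late-numbered entries as the whole cause. The trend may add to the gap between clustered and single-hairpin miRNAs. Against single-hairpin miRNAs matched in those 6 abundance classes, the gap was still -0.26, with 0 of 10000 draws as low. The draws treat miRNAs as independent, and the matching is coarse. Its top class runs from 9.88 to 17.41 log2 CPM, with clustered miR-19b-3p at 17.41 and single-hairpin miR-223-3p at 14.89. Abundance thus stays open as a cause of part of the remaining gap. The 8 lists called by camera were not matched on abundance, so the trend may add to their calls too. A shift in Argonaute loading was not tested.

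One hypothesis was that hairpins with a weaker predicted fold depend more on ERH. Across 313 hairpins, the partial rank correlation of fold energy per nucleotide with log2 fold change, given abundance, was -0.19 (permutation test, p = 0.00074, adjusted p = 0.0022 over 3 tests), so more stable hairpins tended to lie higher. Within 109 clustered and within 204 single hairpins it was -0.18 and -0.15 (adjusted p = 0.069 and 0.053). The relation is weak, and the hairpins, some of which share a transcript, are not independent.

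The number of calls was also counted for the other ways of splitting the 4 libraries. The real split, 1 of 3, gave 236 and the highest of the others gave 0 (edgeR, with at most 1 at an unadjusted p under 0.05). Each other split puts 1 knockdown and 1 control library in each group. A real effect of knockdown would then widen the spread within groups, so few calls there were likely in advance. With 3 splits no share under 0.05 can be reached.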
